A study of Mus musculus with 2 samples.

How the data were processed

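DNase-seq maps chromatin that the nuclease DNase I can cut, which marks promoters, enhancers and other regulatory elements. Per the labels, nuclei came from the facial prominences (the outgrowths that form the face) of healthy B6NCrl mouse embryos at day 11.5, with male and female embryos pooled. The series held 2 libraries of this single group, labelled biological replicates 1 and 2 and made from separate biosamples. Replicate 1 was sequenced on HiSeq 2500 and NextSeq 500 instruments, and replicate 2 on these and an earlier HiSeq model, per the labels. With 1 group there was no comparison between conditions: the libraries were compared with each other, and the accessible sites found in both were then described.

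Each library had a file of peaks and a file of hotspots (wider enriched regions), both called by the authors on that library alone and not on pooled libraries, on genome build mm10, per the files' accompanying notes. The aligner, the caller and their versions are not given in the sources used here. Each peak was 150 bp wide and carried a signal value deposited by the authors, called strength below. Strength was a whole number that reached 150 only on the mitochondrial genome of replicate 2 and never exceeded it, so that it is bounded and compresses differences between strong peaks. What it counts and how it relates to depth is not given in the sources used here. It was therefore used only to rank, filter and describe peaks within a list and was correlated across matched peaks. The exception is a ratio between the libraries in the closing section, used to compare X with the autosomes. The columns for p and q in the deposited peak files were empty. Each hotspot had a deposited −log10 q value between 1.30 and 100, a ceiling that 29.4% of the hotspots of replicate 1 and 35.2% of those of replicate 2 reached. The deposited hotspot score, which rises with the −log10 q, was not used in any test. No read totals were in the files used here, so that the depth of each library is unknown, and no interval below covers the error of read sampling.

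Peaks on chromosomes 1 to 19 and X were analysed. Peaks on Y, on the mitochondrial genome and on unplaced scaffolds were left out, because Y and scaffold sequence is repetitive and the mitochondrial genome has no nucleosomes, and their numbers are given in the closing section. Gene models came from GENCODE release M21 for mouse and sequence from GRCm38 patch p6, the same build as mm10. Protein-coding genes on the chromosomes analysed numbered 21644, with 41129 distinct transcription start sites (TSSs). Coordinates are 1-based and inclusive.

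A peak counted as shared when a peak of the other library covered at least 75 bp (50%) of it. The set called shared peaks consists of the replicate 1 peaks with such a match in replicate 2. Chance was estimated with 100 random placements of the other library's peaks on the same chromosomes, outside runs of N of at least 1000 bp. The smallest p that these placements allow is 0.0099, or 0.0198 for a 2-sided test. Shares carry exact 95% binomial intervals (Wilson intervals for the shares of matched peaks and for chromosome X), which treat peaks as independent and cover counting error only. Peaks are not replicates: intervals and p-values over peaks or genes describe these libraries, and n = 2 throughout for the spread between libraries. A peak whose centre lay within 1 kb of a protein-coding TSS was a promoter peak, and other peaks were distal and were classed as exonic, intronic or intergenic. Each distal peak was assigned to the gene with the nearest protein-coding TSS, which need not be the gene it regulates. A gene's interval is the stretch of genome nearest to its TSSs, and the expected number of distal peaks shares all 62957 out in proportion to interval size.

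The 18 gene lists covered craniofacial mesenchyme and neural crest transcription factors, pharyngeal arch patterning, facial signalling, cleft lip and palate genes, facial ectoderm and epithelium, olfactory placode and lens, Hox genes, cartilage and bone, skeletal muscle, endothelium, erythroid cells, macrophages and leukocytes, neurons and neural tube, limb and trunk regional genes, heart, liver with pancreas and gut, pluripotency and germ line, and housekeeping genes. Of the 448 distinct genes listed, 447 were in the annotation. Erythroid Ahsp was not matched by name. Some genes stood in more than 1 list, most often among the cleft lip and palate genes, of which 19 of 33 were also in another list. For each list the share of genes with a shared promoter peak was compared with 10000 random lists of the same size matched in 10 classes of promoter CpG observed/expected ratio, taken over 1000 bp around the TSS. The mean of log2(1 + shared distal peaks), with a pseudocount of 1, was compared with 10000 random lists matched in 10 classes of interval size. Both were 2-sided permutation tests whose smallest p is 0.00020, with Benjamini-Hochberg adjustment over the 18 lists and a threshold of 0.05 on the adjusted p. Differences between lists were tested by permutation of the genes' excess over their matched classes.

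Sites of 30 consensus sequences, and pairs of a TWIST type E-box and a homeodomain site with at most 20 bp between them, were counted on both strands of shared peaks and of 150 bp windows 2 kb to either side that met no peak or hotspot of either library. Background windows were weighted to the GC content of the peaks in steps of 2.5%. Odds ratios are given with 95% intervals, separately for distal and promoter peaks. Motifs without any site in the peaks or in the weighted background were not tested.

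The gene lists, the consensus sequences, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise. Named are the 20 genes with the most shared distal peaks; the 20 with the most relative to the number expected from their interval, among genes with at least 10; the 10 strongest shared peaks by mean rank of strength in both libraries; up to 4 members of each list with and without a shared promoter peak, by number of distal peaks; and the 4 Hox clusters. Some genes that this rule names are left out of the text. The alternatives were an overlap of 1 bp or of 90%, the 50000 strongest peaks of each library, hotspots in place of peaks, promoter windows of 500 or 2500 bp, every annotated TSS (130588 positions), random lists without matching, all distal peaks within 100 kb of a TSS, background windows 10 kb away, no weighting by GC content, and each library alone.

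The functions were tested on simulated data with known answers. For shared peaks, 3 sets of 40000 placed peaks gave overlap within 0.198 percentage points of the planted share. For the genomic distribution, all of 1000 random positions received the same class and gene distance from a plain loop (100%). For the distal test of lists of 25 genes drawn from the 21644, 4.80% of 1000 simulated lists without an effect had p under 0.05, against 27.4% with 1.5 times as many peaks, 68.3% with 2 times and 96.5% with 3 times. For the promoter test the share was 4.20% without an effect, 49.9% with a share lower by 20 percentage points and 98.2% with one lower by 40. For motifs, 96.8% of 279 intervals held 1 when nothing was planted in 9999 windows, and sites planted in 10.0% of windows were recovered at 10.0%. For pairs of sites, 1000 planted pairs were found once each with their spacing and order (100%). The count of shared peaks was checked with bedtools 2.31.1, which gave the same 85950. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.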

Results

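Accessible chromatin was mapped by DNase-seq in the facial prominences of mouse embryos at day 11.5, when the outgrowths that build the face are mostly neural crest mesenchyme under a sheet of ectoderm. The data were 2 libraries of 1 group, biological replicates 1 and 2, each from pooled male and female embryos. On chromosomes 1 to 19 and X, replicate 1 had 209299 peaks and replicate 2 had 219061, a mean of 214180 ± 6903 (SD, n = 2). Hotspots numbered 178464 and 188815 and covered 58.9 Mb and 66.7 Mb, with median lengths of 201 and 240 bp. Every peak lay in a hotspot of its own library. Strength, the authors' own value per peak, had a median of 16 in replicate 1 (quartiles 7 and 31) and 42 in replicate 2 (quartiles 29 and 66). These medians were not compared as levels, because the scale of the strength value relative to depth is unknown, as is the depth of either library.

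The comparison that the design gives is that of the replicates: which sites opened in both maps of the embryonic face, and which in 1 of them. Of the replicate 1 peaks, 85950 (41.1%, Wilson 95% interval 40.9 to 41.3) had a match in replicate 2, and 84369 replicate 2 peaks (38.5%, 38.3 to 38.7) had one in replicate 1. The mean was 39.8%, taken over both directions of the same overlap, so that it carries no spread between replicates. Random placement of the other library's peaks gave 1.33% and 1.27%, so that the overlap was 30.8 and 30.3 times the random mean. The permutation p over 100 placements was 0.0099, the smallest they allow (1-sided). Matching rose with strength. Among 10 equal classes of strength, the strongest class matched at 94.6% in replicate 1 and 93.2% in replicate 2, while the weakest matched at 0.210% and 5.82%. The 3 weakest classes of replicate 1 held 62790 peaks of strength 8 or less and matched at 0.916%, below the 1.31% of random placements. The 65719 peaks of the 3 weakest classes of replicate 2, of strength 31 or less, matched at 8.37%. Across the 85950 matched peaks, which are not independent replicates, the authors' strength values had a Pearson correlation of 0.904 and a Spearman correlation of 0.891. The Pearson correlation was 0.933 over promoter peaks and 0.844 over distal peaks. The share that matched depended on the definition: it was 12.3% when 90% of a peak had to be covered and 75.1% among the 50000 strongest peaks of each library.

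**Figure D1:**
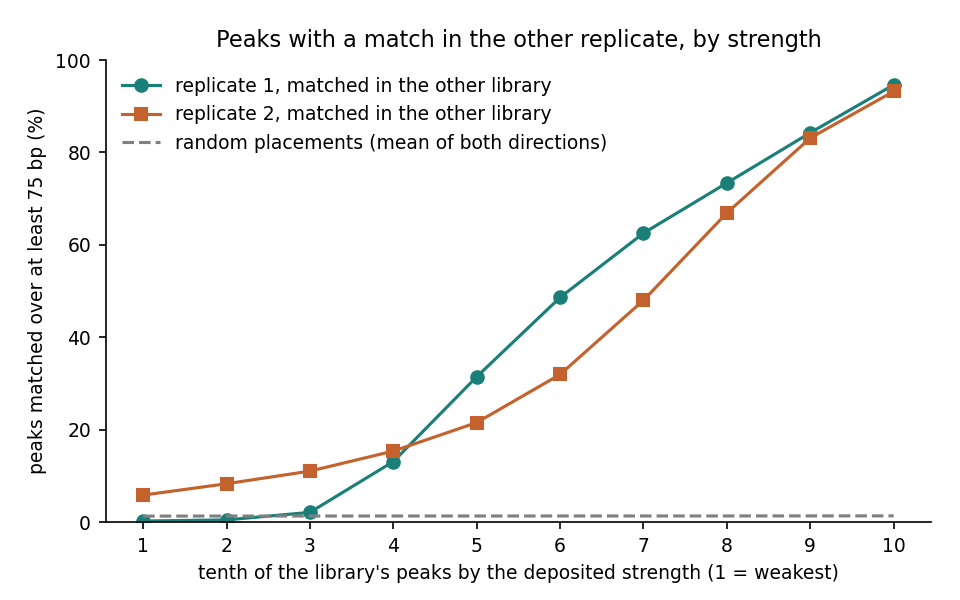
Percent of peaks matched over at least 75 bp in the other replicate (vertical axis) in 10 equal classes of the authors' strength within each library (horizontal axis, 1 is the weakest), for replicates 1 and 2, with the mean of 100 random placements as a dashed line. The strongest class matched at 94.6% and 93.2%, and the weakest class of replicate 1 at 0.210%, under the random mean.

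The next question was where in the genome the accessible sites of the face lay. Of the shared peaks, 22993 (26.8%) were at promoters of protein-coding genes, 12.3 times the 2.18% of random placements. Exons held 3.39% (random 2.55%), introns 31.2% (37.4%) and intergenic sequence 38.6% (57.9%). Each of these differed from random placement with a 2-sided permutation p of 0.0198, the smallest that 100 placements allow. Using the peaks of each library alone, the promoter share was 17.1% and 17.9%, a mean of 17.5% ± 0.521 (SD, n = 2), since unmatched peaks lay at promoters less often (10.4% in replicate 1 and 12.1% in replicate 2). Among the 50000 strongest peaks of each library it was 44.2%. Shared promoter peaks had median strengths of 61 and 102 in replicates 1 and 2, against 28 and 63 for shared intergenic peaks and 27 and 63 for intronic ones, and their median GC content was 64.7%. Distal peaks lay a median of 30.7 kb from the nearest protein-coding TSS, 73.5% of them beyond 10 kb and 22.8% beyond 100 kb.

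The 10 strongest shared peaks all lay at promoters. First by mean rank was the promoter of Hjurp, the chaperone that loads the centromeric histone CENP-A (mm10 chromosome 1, 88277536 to 88277685, over exon sequence 22 bp from a TSS), with strengths of 134 and 149, the highest of either library on the chromosomes analysed. The next were at the translation factor gene Eif4g2 (chromosome 7, 111083096 to 111083245), the rootlet gene Crocc (chromosome 4, 141060576 to 141060725), the histone-binding gene Rbbp4 (chromosome 4, 129335336 to 129335485) and the Integrator subunit gene Ints7 (chromosome 1, 191575576 to 191575725). The poly(A)-binding protein gene Pabpc1 (chromosome 15, 36609096 to 36609245), the mitochondrial chaperonin gene Hspd1 (chromosome 1, 55087996 to 55088145), the actin methyltransferase gene Setd3, the PHD finger gene Phf12 and the RNA-binding protein gene Lsm14a completed the 10, with strengths of 119 or more in replicate 1 and 144 or more in replicate 2.

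Across chromosomes, shared peaks were densest on gene-rich chromosomes 11 (50.8 per Mb of sequence) and 19 (46.6 per Mb) and sparsest on X (12.0 per Mb), followed by 14 (28.0 per Mb). Over the 20 chromosomes the density of shared peaks went with that of protein-coding genes, with a Pearson correlation of 0.755 and a Spearman correlation of 0.874. Both had a 2-sided permutation p of 2.0e-05, the smallest that 100000 permutations allow, and this was the only such relation computed. Without chromosomes 7 and 11, farthest from the median gene density, Pearson's r was 0.760. X held 1.77% of the peaks of replicate 1 (95% interval 1.71 to 1.83) and 2.48% of those of replicate 2 (2.42 to 2.55), but among the stronger 5 of 10 strength classes the order turned, with 2.11% (2.02 to 2.20) and 1.88% (1.804 to 1.965).

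Promoter accessibility was then set against lists of genes for the cell types of the face and of other organs. Of 21644 protein-coding genes, 13896 (64.2%) had a shared promoter peak, and 67.3% and 70.8% had a promoter peak in replicates 1 and 2. The share followed CpG content: it was 5.80% among the 5411 genes with the lowest promoter CpG ratio and 97.2% among the 5411 with the highest. Lists were therefore compared with random lists matched on CpG ratio. Of the 18 lists, 3 passed the threshold, all with fewer open promoters than matched lists, and 15 did not. Where matched lists stood near 100%, the test could hardly pass upward. Housekeeping genes at 100% did not pass (adjusted permutation p 0.620), nor did craniofacial transcription factors at 100% in replicate 1 alone (0.140). For such lists the test cannot tell whether open promoters are in excess.

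Hox genes, which pattern the trunk, limbs and hindbrain and are largely silent in the neural crest that builds the upper face, had a shared promoter peak at 15 of 39 genes (38.5%) against 88.1% in matched random lists (95% of them between 79.5% and 97.4%), with an adjusted permutation p of 0.0018. In each library alone the share was 55.1% ± 1.81 (SD, n = 2), also past the threshold. Hox genes lie side by side in a few clusters, while random lists were drawn without regard to position. The range and the p treat these neighbours as independent, so that they can overstate the certainty of the Hox result. The same holds for the test of Hox distal peaks below. The pluripotency and germ line list had 5 of 25 (against 59.9% of genes in matched lists, adjusted permutation p 0.0018), with a peak at Tex14, Tfcp2l1, Dazl and Prm1 and none at Ddx4, Gdf9, Sycp1 and Tnp2. The liver, pancreas and gut list had 5 of 29 (17.2% against 42.3%, adjusted permutation p 0.0024), with a peak at the transcription factor genes Foxa1, Sox17 and Pdx1, none in either library at Serpina1a, Cyp3a11 and Lgals4, and one in replicate 2 only at Fgb. This last call was lost with replicate 1 alone (27.6% against 46.2%, adjusted permutation p 0.0624) and with a promoter window of 2500 bp (adjusted permutation p 0.554).

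The lists for the face had open promoters at most genes, as did matched random lists. Craniofacial mesenchyme and neural crest transcription factors had a shared promoter peak at 48 of 51 genes (94.1% against 91.3%, adjusted permutation p 0.848), among them the nuclear receptors Nr2f1 and Nr2f2, the cartilage regulator Sox9 and Mecom. The other 3 members, Tfap2b and Six2 among them, each had a promoter peak in both libraries but no shared one, so that each library alone gave 100%. Pharyngeal arch patterning genes had 18 of 20 (against 91.1%), where the other members, Dlx4 and Fgf8, had a promoter peak in both libraries but no shared one, facial signalling genes 30 of 35 (85.7% against 92.4%), cleft lip and palate genes 31 of 33 (93.9% against 87.8%), and olfactory placode and lens genes 17 of 19 (89.5% against 88.1%), without the crystallin genes Cryaa and Cryab. Facial ectoderm and epithelium genes had 16 of 25 (64.0% against 72.9%). Grhl2, Epcam and Wnt4 had a shared peak, the keratin genes Krt5 and Krt14 had no promoter peak in either library, and Krt15 and the claudin gene Cldn6 had one in replicate 2 only. In replicate 2 alone the ectoderm list stood above matched lists (88.0% against 80.8%), while with the 50000 strongest peaks it passed the threshold with a difference of −29.1 percentage points (adjusted permutation p 0.00216). Each library alone turned the pharyngeal arch list above matched lists (100% against 93.7% and 95.3%), as it did facial signalling (97.1% against 94.9% and 96.3%), and put olfactory placode and lens below them (89.5% against 91.0% and 93.2%). With all shared peaks none of these lists passed the threshold (adjusted permutation p between 0.614 and 1 for the 5).

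Markers of other cell types gave 14 of 22 genes for cartilage and bone (63.6% against 56.6%), 9 of 21 for skeletal muscle (42.9% against 42.8%), 21 of 26 for neurons and neural tube (80.8% against 85.97%), 13 of 19 for limb and trunk regional genes (68.4% against 79.3%) and 11 of 20 for heart (against 52.7%). Endothelial genes had 10 of 23 (43.5% against 60.0%), with an adjusted permutation p of 0.213, open at Flt1, Fli1, Kdr and Sox17, and in replicate 2 alone they turned to more than matched lists (78.3% against 69.6%), without passing, while with the 50000 strongest peaks they passed with a share lower by 34.6 percentage points (adjusted permutation p 0.000900). Erythroid genes had 5 of 20 (against 20.9%) and were without a peak at Gata1, Hba-a1 and Hba-a2. Macrophage and leukocyte genes had 3 of 21 (14.3% against 23.0%), namely Irf8, Coro1a and Cd68. Housekeeping genes had 31 of 31 (100% against 94.2%), which did not pass the threshold (adjusted permutation p 0.620). In replicate 2 alone the heart list passed with a higher share (85.0% against 60.6%, adjusted permutation p 0.0135), and in replicate 1 alone it did not (65.0% against 55.9%). Without matching on CpG 10 lists passed, and not all of them with a lower share than random lists.

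Within the 4 Hox clusters, open promoters were not confined to 1 end. In Hoxa (chromosome 6) 6 of 11 genes had a shared promoter peak, Hoxa10 and Hoxa13 among them. In Hoxb (chromosome 11, 96194316 to 96368256) 4 of 10 had one, Hoxb2, Hoxb4, Hoxb5 and Hoxb13, and in Hoxc (chromosome 15, 102921103 to 103036852) 4 of 9, Hoxc4, Hoxc5, Hoxc10 and Hoxc13. In Hoxd (chromosome 2, 74668310 to 74765142) only Hoxd1 of 9 had one. With replicates 1 and 2 alone, 2 and 4 Hoxd genes had a promoter peak, as did 7 and 7 in Hoxa, 8 and 5 in Hoxb and 5 and 5 in Hoxc. By paralog group, 7 of 12 genes of groups 1 to 4, 3 of 11 of groups 5 to 8 and 5 of 16 of groups 9 to 13 had a shared promoter peak. With each library alone the numbers were 9, 6 and 7 in replicate 1 and 7, 7 and 7 in replicate 2, so that the low middle group was not kept. The difference between these groups was not tested. Replicate 1 had more peaks than replicate 2 over each cluster (92 against 34 in Hoxa, 80 against 43 in Hoxb, 45 against 17 in Hoxc and 50 against 12 in Hoxd), of which 17, 19, 6 and 7 were shared.

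**Figure D2:**
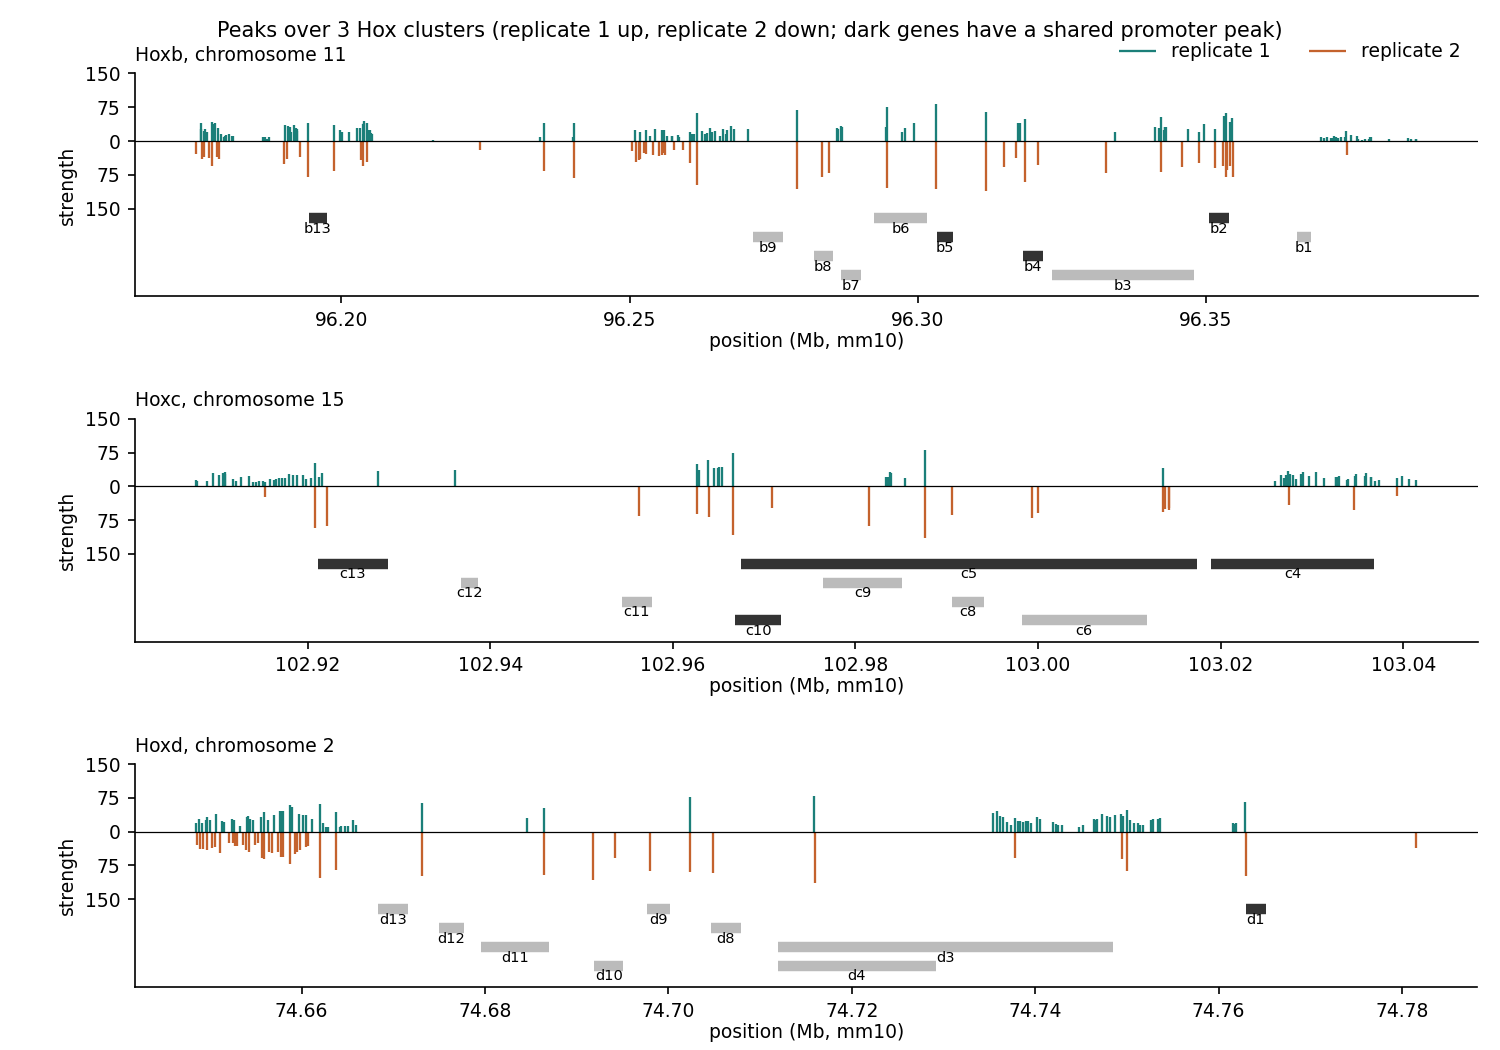
Peaks over the Hoxb, Hoxc and Hoxd clusters in mm10 coordinates (Mb), with the authors' strength of each peak drawn upward for replicate 1 and downward for replicate 2, and genes as bars below, dark where a shared promoter peak was present. Of the 10 Hoxb genes 4 are dark, of the 9 Hoxc genes 4, and of the 9 Hoxd genes only Hoxd1.

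Distal peaks were counted next, to ask whether regulators of the face carried more candidate regulatory elements than other genes with as much surrounding sequence. Of the 21644 genes 13588 (62.8%) had at least 1 shared distal peak. Of the 18 lists 14 had more distal peaks than matched random lists and passed the threshold, and none passed with fewer. The largest difference in shared peaks was that of craniofacial mesenchyme and neural crest transcription factors, with a mean of 4.16 on the log2(1 + peaks) scale against 2.45 in matched lists. Taken back from the log2 scale, this difference is a ratio of 3.28 between geometric means of 1 + peaks. The adjusted permutation p was 0.00045, from the smallest p that the permutations allow. Using the peaks of each library alone the difference was 1.80 ± 0.16 (log2 units, SD, n = 2). Pharyngeal arch patterning genes were ahead in each library alone, with 2.05 in replicate 1 and 1.73 in replicate 2, against 1.92 and 1.69 for the craniofacial list. With all distal peaks within 100 kb of a TSS, the lists for olfactory placode and lens (1.59), pharyngeal arch (1.57) and limb and trunk (1.54) were ahead of the craniofacial one (1.496). The list's 51 genes held 1136 of the shared distal peaks, with a median of 19 per gene, and 43 of the 51 had more than their interval predicts. Nr2f2 had 85 against 31.9 expected, Sox9 51 against 30.6, Nr2f1 46 against 35.0, Mecom 44 against 24.8 and Six2 25 against 5.13, while Tfap2b had 15 against 18.6.

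Pharyngeal arch patterning genes followed with a mean of 3.57 against 2.00, with Mef2c (47 distal peaks), Dlx6 (33), Hand2 (31) and Lhx8 (25), where the endothelin pathway genes Dlx6 and Hand2 define the lower jaw. Means for limb and trunk regional genes were 3.73 against 2.18, with Tbx3 (38), Pax2 (32), Uncx (32) and Tbx15 (29) among them, for olfactory placode and lens 3.59 against 2.20, with Sox2 (42), Six3 (41), Pax6 (34) and Maf (32), and for facial signalling 3.58 against 2.35, with Bmp2 (27), Bmp7 (26), Fgfr2 (25) and Gli3 (24). Cleft lip and palate genes had 3.13 against 2.07, with Sox9, Fgfr2, Tfap2a (24) and Msx1 (22) among them, and with 3 at the epithelial regulator Trp63 against 11.5 expected. Neurons and neural tube gave 3.19 against 2.23, with Lmx1b (26), Sox1 (23), Dbx1 (22) and Rbfox3 (21) among members with an open promoter, and cartilage and bone 2.91 against 1.89, with Sox9, Sox6 (32), Sox5 (30) and the collagen gene Col1a1 (19 against 2.26 expected). All of these had the adjusted permutation p of 0.00045.

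Smaller differences were past the threshold for heart (2.40 against 1.52, adjusted permutation p 0.00098), with Gata6 at 16 and Tbx20 at 14, for skeletal muscle (2.06 against 1.29, 0.00080), with Tcf21 at 16, for facial ectoderm and epithelium (2.02 against 1.40, 0.0030), with Grhl2 at 11, for endothelium (2.17 against 1.62, 0.0152), with Flt1 at 17 and Fli1 at 14, for housekeeping genes (1.29 against 0.79, 0.00098), with Eef1a1 at 11, and for Hox genes (0.91 against 0.55, 0.0036), with 6 at Hoxb13. The lists of erythroid cells (0.75 against 0.80, adjusted permutation p 0.807), pluripotency and germ line (1.36 against 1.31, 0.807), macrophages and leukocytes (1.38 against 1.02, 0.0803) and liver, pancreas and gut (1.89 against 1.51, 0.0610) did not pass. Endothelium and heart no longer passed among the 50000 strongest peaks, and the liver, pancreas and gut list passed in replicate 1 alone (difference 0.50, adjusted permutation p 0.0485) but not in replicate 2 alone (0.25, 0.284). That list also passed without matching on interval size (0.58, 0.0282), with 50 classes of it (0.41, 0.04296) and with matching on promoter peaks (0.69, 0.000654). The macrophage list passed within 100 kb (0.63, 0.0221), with the 50000 strongest peaks (0.55, 0.0036) and with matching on promoter peaks (0.58, 0.0036). The matching on 50 classes and on promoter peaks was chosen after seeing the data. The Hox difference was 1.34 in replicate 1 alone and 0.52 in replicate 2 alone, and in replicate 2 alone that of facial ectoderm was 1.03, of endothelium 0.82 and of housekeeping genes 0.75. The craniofacial list exceeded the limb and trunk, heart and neural lists pooled (62 genes, which include structural genes of heart and neurons such as Ryr2 and Syt1) by 0.63 log2 units (95% interval 0.27 to 0.99, 2-sided permutation p 0.00102). Against each alone, it exceeded heart by 0.83 (adjusted permutation p 0.00558) and the neural list by 0.76 (0.00615). It was 0.17 above the limb and trunk list, with an interval of −0.28 to 0.63 that includes 0 (adjusted permutation p 0.492).

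**Figure D3:**
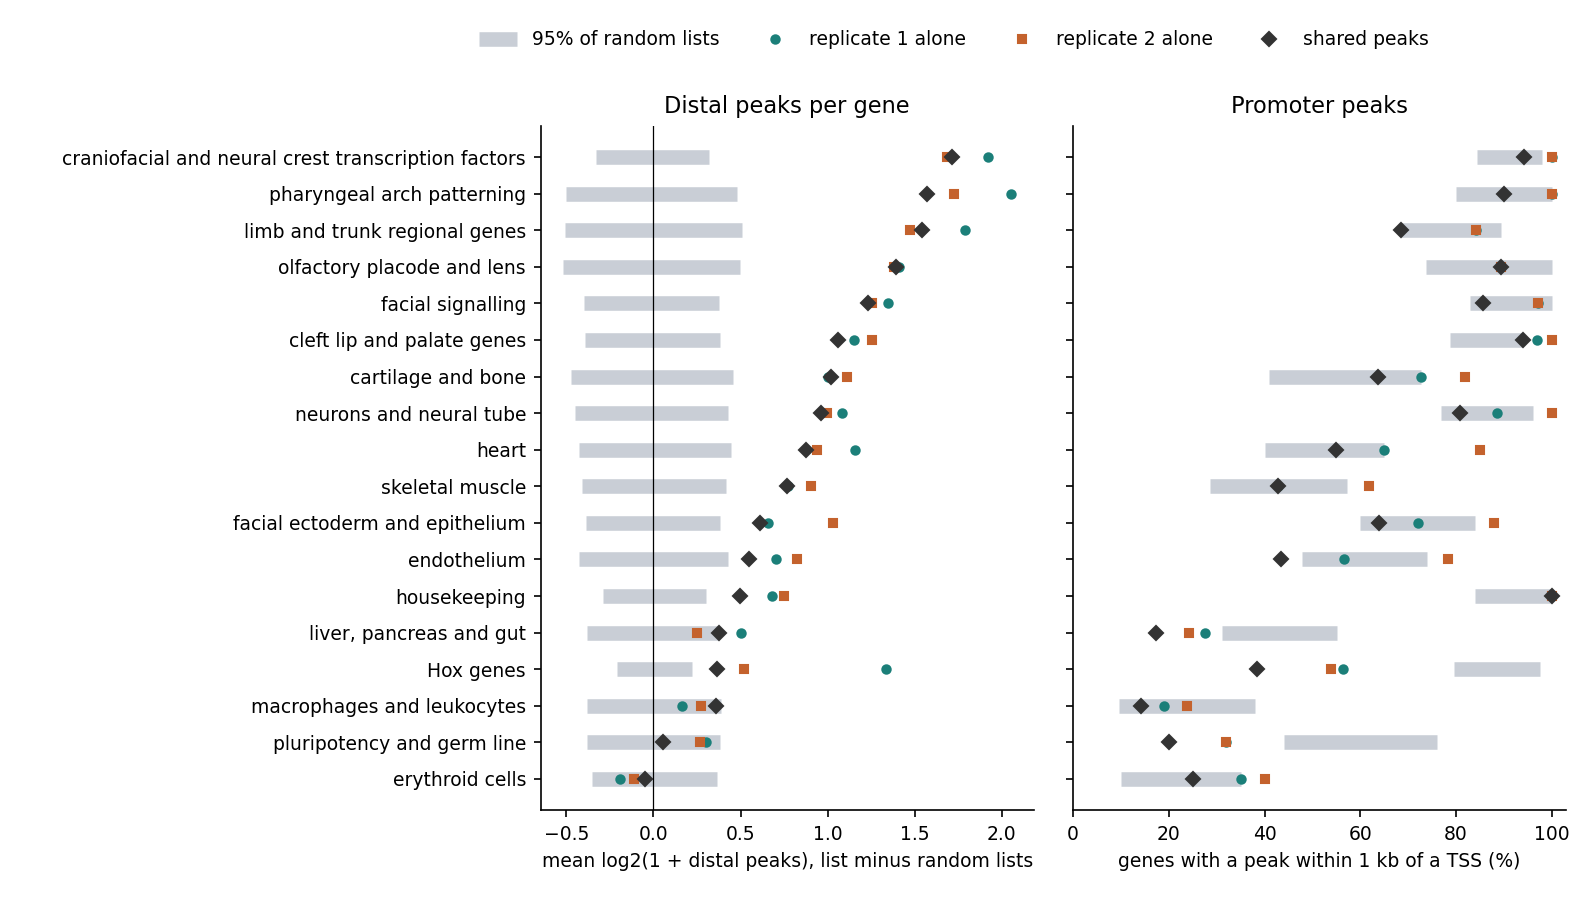
Left, mean log2(1 + distal peaks) of each gene list minus the mean of its matched random lists, and right, percent of its genes with a promoter peak within 1 kb of a TSS, for shared peaks (diamonds), replicate 1 alone (circles) and replicate 2 alone (squares), with bars for the central 95% of random lists for shared peaks. Craniofacial transcription factors stand at 1.71 on the left, and Hox genes at 38.5% on the right, below their bar of 79.5% to 97.4%.

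Single genes were ranked next by their number of shared distal peaks. The 20 genes with the most, all with an open promoter, had 44 to 119 in intervals of 366 to 2760 kb. Zfp608, a zinc finger gene (chromosome 18, 54888048 to 54992555), led with 119 against 31.1 expected, spread from 54453056 to 55695225. The nuclear receptor gene Nr2f2 (chromosome 7, 70351944 to 70366735) had 85, the zinc finger homeobox gene Zfhx3 (chromosome 8, 107942644 to 108961630) 84 against 32.8 expected, and Auts2 (chromosome 5, 131437333 to 132543344) 75 against 47.2. The mRNA decay factor gene Zfp36l1 (chromosome 12, 80107754 to 80113013) had 63 against 11.8, the largest excess of the 20 at 5.35 times the expected number, followed by the homeobox gene Barhl2 (46 against 8.97), Zfp608, Ubash3b (52 against 14.7) and the coactivator gene Zmiz1 (50 against 14.7). Sox11 (57), Pou3f3 (47), Epha4 (47), Zfp536 (45) and Nfib (44) were also above expectation, by 1.45 to 2.77 times. The axon guidance receptor Robo1 (54 against 50.2), the teneurin Tenm3 (66 against 67.6), the latrophilin Adgrl2 (54 against 57.7) and the mesenchymal cadherin Cdh11 (53 against 57.4) had about as many as their intervals predict. The ranking depended on the peaks used: of these 20 genes, 8 stayed among the top 20 with the 50000 strongest peaks, 11 with replicate 2 alone and 10 with replicate 1 alone.

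Some of the strongest distal peaks of these genes lay far from their TSS. That of Sox9 was intergenic, 383 kb downstream (chromosome 11, 113165176 to 113165325), with strengths of 77 and 111 in replicates 1 and 2 and an AP-2 site. That of Cdh11 was intergenic, 624 kb upstream (chromosome 8, 103409196 to 103409345, strengths 69 and 117), with a TEAD site, that of Sox11 260 kb downstream (chromosome 12, 27082776 to 27082925, strengths 65 and 117), with TWIST type E-box and SOX sites, and that of Mef2c 170 kb downstream (chromosome 13, 83745136 to 83745285, strengths 85 and 117). Nearer ones were at Zmiz1, 1.47 kb upstream (chromosome 14, 25457676 to 25457825, strengths 114 and 144), and at Zfp36l1, 19.8 kb upstream (chromosome 12, 80132776 to 80132925, strengths 88 and 124).

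**Figure D4:**
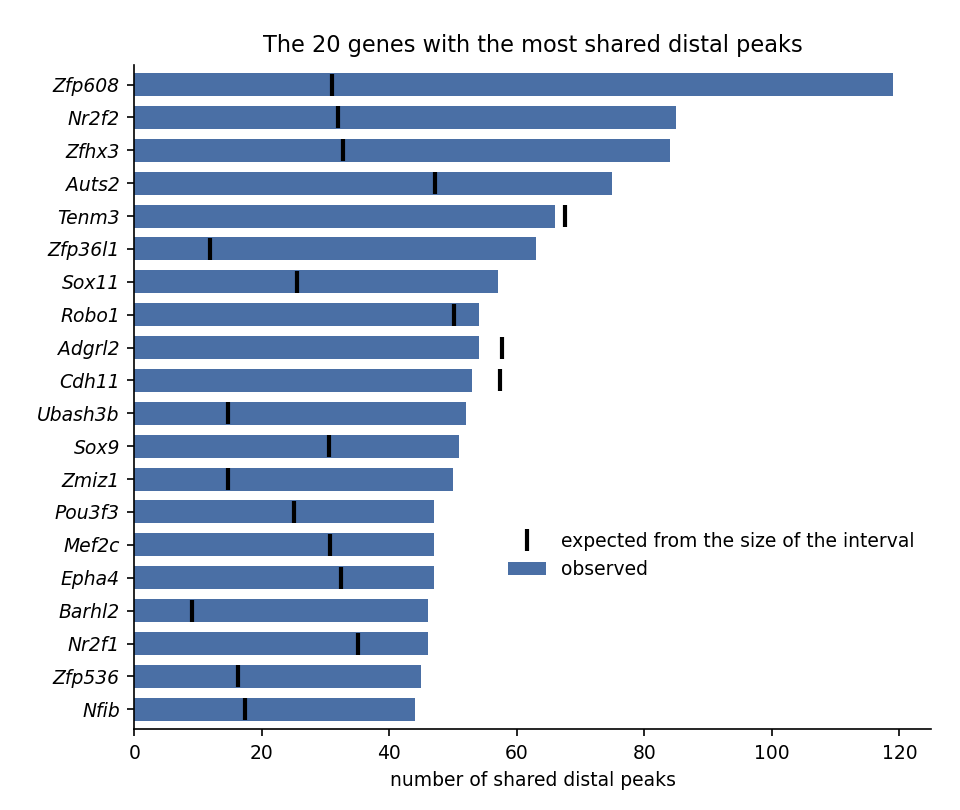
Number of shared distal peaks nearest to each of the 20 genes with the most (bars) and the number expected from the size of the gene's interval (black marks). Zfp608 had 119 against 31.1 expected, while Tenm3 had 66 against 67.6.

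Relative to interval size, the 20 genes in front had 12.5 to 42.6 times the expected number, in short intervals of 12.5 to 74.1 kb. First was Zic2, a zinc finger gene of forebrain and neural crest development (chromosome 14, 122475435 to 122479852), with 13 against 0.305 expected. It was followed by the Polycomb gene Cbx8 (chromosome 11, 119036305 to 119040969), with 22 against 0.774, and by 9230102O04Rik, Abt1 and Hist1h4h at 23.6 to 25.1 times. Abt1, Hist1h4h, Prss16, Zfp184, Btn1a1 and Btn2a2 all lay in or beside the histone gene cluster of chromosome 13, between 21945094 and 23531519. A930004D18Rik, Gpr84, Aurkb, Setd1b, Golga2, Rdm1 and the limb and brain regulator Sp9 (17 against 1.202) were also among the 20. The NK cell receptor gene Klrb1c and the odorant receptor gene Olfr1423 were among them without a promoter peak in either library, at 15.0 and 14.1 times. Because distal means away from protein-coding TSSs, these counts can include peaks at the TSSs of other genes.

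Sequence motifs were counted to ask which transcription factor families' sites marked the distal peaks of the face. Of 31 motifs tested in 62928 distal peaks, 22 were more frequent than in flanking windows matched on GC content, 3 were less frequent, and for 6 the 95% interval included 1. The site of CTCF, the boundary and loop factor, was in 12.4% of distal peaks and 0.225% of the background, an odds ratio of 62.9 (95% interval 51.2 to 77.3). In all distal peaks of each library, it was 26.7 (24.0 to 29.8) in replicate 1 and 28.0 (25.2 to 31.1) in replicate 2. Sites of NRF1 (8.75, 3.24 to 23.7), the neuronal gene repressor REST (4.85, 3.75 to 6.27) and CREB (3.67, 2.73 to 4.95) came next among single motifs and were less enriched in each library alone, at 6.50 and 3.12, 2.66 and 2.41, and 2.39 and 2.61. The NRF1 interval included 1 among the 50000 strongest peaks. Because distal means away from protein-coding TSSs, all these shares can include peaks at the TSSs of other genes.

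Among factors of facial mesenchyme, TWIST type E-boxes were in 18.4% of distal peaks against 12.5% (odds ratio 1.58, 1.52 to 1.63), homeodomain sites in 3.74% against 2.10% (1.81, 1.67 to 1.956, but 0.871 without weighting by GC content) and TEAD sites in 6.04% against 3.45% (1.80, 1.69 to 1.92). Both together, an E-box with a homeodomain site within 20 bp, were more enriched than either: they occurred in 0.296% against 0.0591% (5.01, 3.28 to 7.65), with 2.48 in replicate 1 alone and 4.84 in replicate 2 alone. A CTCF site can itself contain the E-box sequence, so that part of the E-box excess can be CTCF sites. Without peaks with CTCF sites, E-boxes stayed more frequent than in the background. Nuclear factor I sites had an odds ratio of 2.54 (2.17 to 2.98), LEF/TCF sites, read by the Wnt pathway, 1.40 (1.32 to 1.48), AP-2 sites, bound by regulators of neural crest and facial ectoderm, 1.32 (1.25 to 1.39), MEF2 sites 1.86 (1.40 to 2.49, and 1.16 in replicate 1 alone), SP/KLF sites 2.19 (2.00 to 2.41) and ETS sites 2.05 (1.55 to 2.70). Forkhead (1.24), SOX (1.17) and RUNX (1.11) sites were above 1 by less, and without weighting by GC content fell below it (0.768, 0.939 and 0.995). In replicate 1 alone the RUNX interval included 1 (0.992), and NF-Y sites, at 1.08 in shared peaks, turned to 0.891. The 3 motifs less frequent than in the background were GATA sites (0.669, 0.601 to 0.745), PITX type homeodomain sites (0.841, 0.795 to 0.890) and sites of the Six2 family (0.849, 0.792 to 0.910). In replicate 2 alone the PITX interval included 1 (0.988). Sites of facial factors were therefore not all enriched. For MEIS (0.987, 0.948 to 1.03) and PBX-HOX sites (1.05, 0.863 to 1.28) the interval included 1 in shared peaks.

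In promoter peaks 29 motifs could be tested, of which 2 were more frequent than in flanking windows: SP/KLF sites (19.9% against 5.51%, odds ratio 4.25, 95% interval 2.41 to 7.49) and NF-Y sites (12.98% against 2.38%, 6.12, 2.62 to 14.3), both for factors of general promoters. For the other 27 the interval included 1. The intervals were wide, so that an interval with 1 does not show that a motif was not enriched. ETS sites were in 4.03% of promoter peaks against 0.0409% of the background, with a lower limit of 0.174. CREB sites were in 2.07% against 0.339% (odds ratio 6.20, 0.673 to 57.2). TWIST type E-boxes, in 6.11% against 8.83%, were among the motifs that went the other way.

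**Figure D5:**
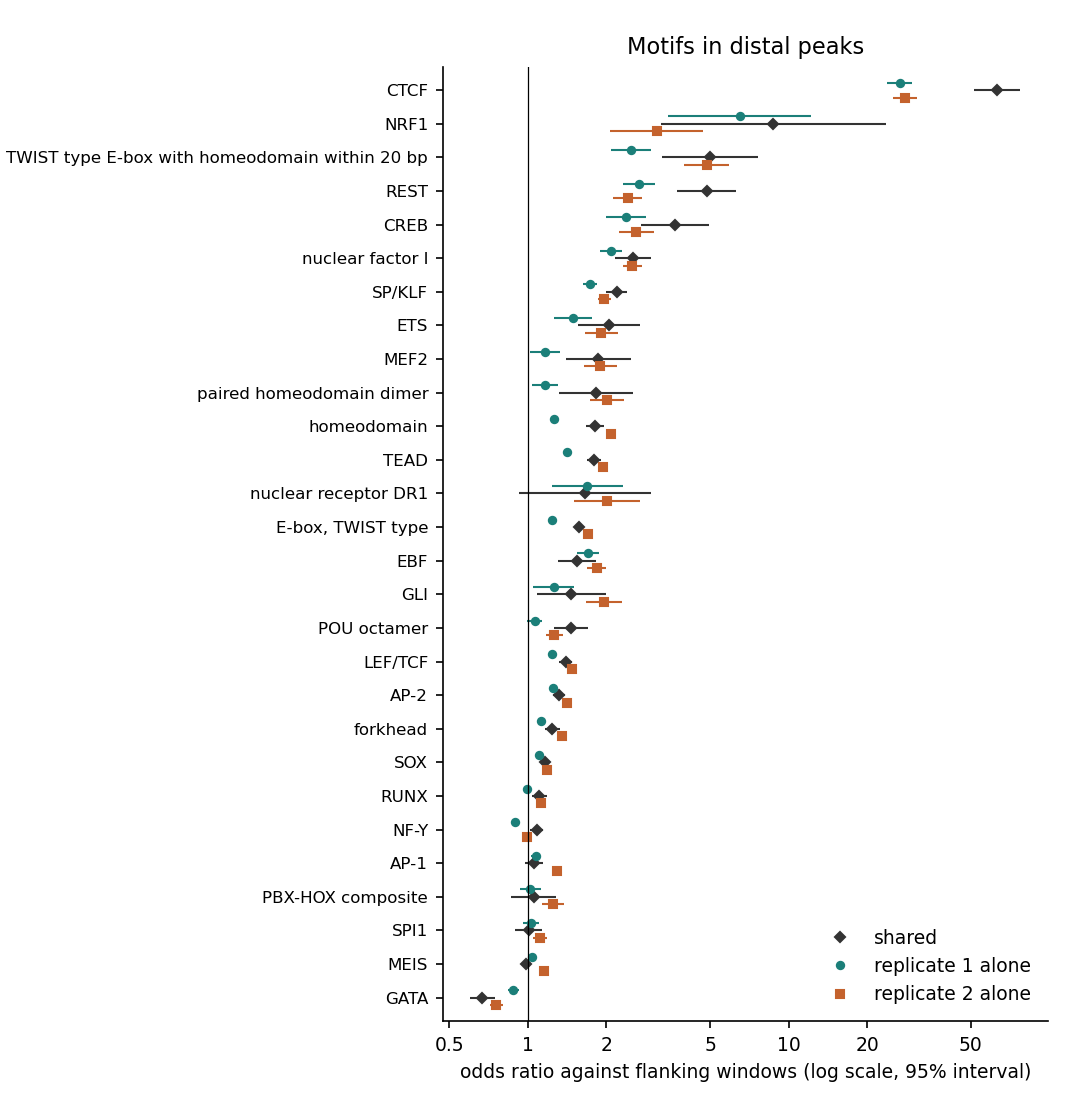
Odds ratio (log scale, with 95% interval) of each motif in distal peaks against flanking windows matched on GC content, for shared peaks, all replicate 1 peaks and all replicate 2 peaks. Of the 31 motifs 28 are drawn, CTCF stands at 62.9 and GATA lies below 1 at 0.669.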

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

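The tests of CTCF sites and of promoters in weak peaks, both tests on chromosome X and the comparison with the limb and trunk list alone were chosen after the result was seen, and the matching on 50 classes of interval size and on promoter peaks was added after seeing the data.

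Peaks also lay in sequence that no comparison of the report uses, and they are listed for that reason alone, without a test. Chromosome Y held 139 peaks in replicate 1 and 51 in replicate 2, of which 30 and 29 matched, with median strengths of 3 and 37. The mitochondrial genome held 30 peaks in replicate 1 and 31 in replicate 2. Unplaced scaffolds held 385 and 256 peaks.

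The 62790 weakest peaks of replicate 1 had almost no counterpart in replicate 2. Whether some were real sites that replicate 2 missed stays open: their CTCF odds ratio was 1.26 (95% interval 0.922 to 1.71) against 9.12 (7.65 to 10.9) in the weakest peaks of replicate 2, yet 10 of 31 motifs lay above 1, among them EBF (1.92, 1.53 to 2.41), the E-box and homeodomain pair (1.53, 1.15 to 2.03) and nuclear factor I (1.36, 1.09 to 1.70), and 2 lay below. That all were calls spread evenly at random was argued against by the promoter share outside hotspots with a stronger peak, 0.874% against 1.202% to 1.438% in random placements. The share was lower than random, and the placements avoid only runs of N, so that false calls with an uneven spread stay open. Whether they were calls in repeated sequence stays open. Their share of repeat-masked bases, 24.8%, was below the 33.25% to 33.97% of random placements, a result fixed beforehand as evidence against it. But it was above the 14.8% of the weakest replicate 2 peaks and the 9.68% of shared peaks. Random placements also ignore whether reads can be placed in a repeat, so that they are a poor standard here. With a single group no biological explanation was tested.

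Chromosome X held 1.77% of the peaks of replicate 1 and 2.48% of those of replicate 2. That the lower share came from the weaker calls fitted: in the weakest class X held 0.865% in replicate 1 and 5.85% in replicate 2. In the stronger 5 of 10 classes the libraries differed the other way, with 2.11% (2.02 to 2.20) in replicate 1 and 1.88% (1.804 to 1.965) in replicate 2. A larger share of male embryos in replicate 1 stays open: the median log2 strength ratio of replicate 1 to replicate 2 at shared peaks was −0.94 on X, near the low end of the autosomes (−0.96 to −0.85), and strength is bounded and its relation to depth unknown.

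Most lists of developmental genes had more distal peaks than matched random lists. So did the housekeeping list (1.29 against 0.79, adjusted permutation p 0.00098), which is among the 14 below. An excess over matched lists was therefore not limited to developmental genes. Uneven interval sizes within the matched classes were argued against by 50 classes in place of 10, with which all 14 lists stayed past the threshold. An excess of open promoters in the lists was argued against by matching on promoter peaks as well, with which the same 14 stayed. Whether regulators of any region carry as many stays open: the craniofacial list exceeded the limb and trunk, heart and neural lists pooled by 0.63 log2 units (0.27 to 0.99), a result fixed beforehand as evidence against it, but the heart and neural lists also hold structural genes and do not stand for regulators alone. Against the limb and trunk list, of regulators, the difference was 0.17 (−0.28 to 0.63), an interval with both 0 and differences above 0.5, and no biological explanation was tested.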

How the results depend on the processing

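The 50 classes of interval size, the matching on promoter peaks, the omission of peaks with CTCF sites and the alternatives for named genes were chosen after seeing the data. No paired analysis was possible because the series has a single group. Depth is unknown, so that the number of weak peaks, and with it every share of peaks, depends on thresholds the authors set. Where a result changed, the cause was not tested unless stated.

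The matched share of 39.8% became 46.9% with an overlap of 1 bp, 12.3% with 90%, 75.1% with the 50000 strongest peaks and 42.005% for hotspots. The promoter share of 26.8% became 20.5% with a window of 500 bp, 33.4% with 2500 bp and 34.6% with every annotated TSS, as the wider definitions include more sequence, 44.2% with the 50000 strongest peaks, and 17.1% to 17.9% with each library alone. The number of lists past the threshold for promoters, 3, became 10 without matching on CpG and 5 with the 50000 strongest peaks, and lay between 2 and 4 elsewhere. For distal peaks it was 14 and lay between 13 and 16 under all alternatives. The motifs above 1, 22 in number, lay between 15 and 27. Of the 20 genes with the most distal peaks, 8 stayed with the 50000 strongest peaks and 10 to 11 with each library alone.

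Among the single lists for promoters, 70 of the values under alternatives kept direction and side of the threshold, 7 newly passed in the same direction, 2 no longer passed and 29 reversed. Here and below, a reversed value is counted only as reversed, also where it newly passed the threshold. Some of the reversed values without matching on CpG did. The reversed ones, in percentage points relative to random lists, were as follows. With a window of 500 bp, muscle was −6.38. With 2500 bp, pharyngeal arch was 7.28, signalling 0.533, olfactory and lens −0.528, neurons 4.40 and limb and trunk 2.41. Without matching on CpG, pharyngeal arch was 26.0, signalling 21.6, cartilage and bone −0.714, muscle −21.2, erythroid −39.3, neurons 16.6, limb and trunk 4.29 and heart −9.33. With the 50000 strongest peaks, olfactory and lens was −8.32, muscle −11.7, erythroid −1.14 and heart −7.12. In both libraries alone, pharyngeal arch (4.75 to 6.29), signalling (0.877 to 2.24) and olfactory and lens (−3.70 to −1.48) reversed. Reversed in replicate 2 alone and not in replicate 1 alone were ectoderm (7.22, against −4.34 in replicate 1), endothelium (8.64 against −7.35) and neurons (9.18 against −0.396). Reversed in replicate 1 alone and not in replicate 2 alone were muscle (−3.66, against 9.05 in replicate 2) and limb and trunk (2.01 against −0.78).

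For distal peaks of single lists 112 values kept both, 7 newly passed, 2 no longer passed and 5 reversed: without matching on interval size Hox genes were −0.39 and housekeeping genes −0.0254, within 100 kb erythroid genes were 0.18, with the 50000 strongest peaks liver, pancreas and gut was −0.00544, and with matching on promoter peaks erythroid genes were 0.0657 (log2 units).

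For motifs 142 values kept both, 12 newly passed, 10 no longer passed and 20 reversed. With windows 10 kb away SPI1 had an odds ratio of 0.985. Without weighting by GC content the values were 0.871 for homeodomain, 0.620 for the paired dimer, 0.751 for PBX-HOX, 1.07 for MEIS, 0.939 for SOX, 0.768 for forkhead, 0.995 for RUNX and 0.922 for POU. With the 50000 strongest peaks they were 0.921 for PBX-HOX, 0.945 for AP-1, 0.817 for GLI and 0.101 for DR1. In both libraries alone MEIS (1.04 to 1.15) and NF-Y (0.891 to 0.994) reversed, RUNX in replicate 1 alone (0.992, against 1.12 in replicate 2) and a motif with few sites in replicate 2 alone (2.25, against 0.963 in replicate 1). Without peaks with CTCF sites MEIS was 1.01.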

Other observations

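Of the tests in this part, those of the spacing of pairs in shared peaks, of spacing in peaks without any overlap and of CTCF sites near craniofacial genes were chosen after the result was seen.

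Near craniofacial transcription factor genes, a smaller share of distal peaks held a CTCF site than in random lists. Of the 1136 shared distal peaks of that list, 38 (3.35%) held a CTCF site, against a mean of 7.96% (95% between 5.67% and 10.5%) in random lists matched on distal peaks, with a 2-sided permutation p of 0.00020, the smallest possible, and an adjusted p of 0.00080 over 4 motifs. The random lists were not matched on interval size, and most genes of this list had more distal peaks than their interval predicts. The result therefore does not separate fewer CTCF sites from more peaks of other kinds. TWIST type E-boxes were in 16.9% against 19.5% (adjusted p 0.164) and homeodomain sites in 4.31% against 4.34% (adjusted p 0.996). The E-box shares include CTCF sites that contain an E-box, so that they are not independent of the CTCF result.

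The hypothesis that pairs of a TWIST type E-box and a homeodomain site lie near craniofacial transcription factor genes was left open: 1 of the list's 1136 distal peaks held a pair (0.0880%), against a mean of 0.347% (0 to 0.789) in random lists, with a 2-sided permutation p of 0.123. The share was below the random mean, which goes against the hypothesis, but it lay inside the range of random lists. The test therefore does not decide. Pairs lay nearest to 182 genes in all.

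A composite of such sites at a fixed spacing is known from cranial neural crest under the name Coordinator. The hypothesis that both sites fall independently of each other was argued against by their spacing. In shared distal peaks 51 of 193 pairs (26.4%, 95% interval 20.4 to 33.2) had the homeodomain site first with 4 bp between the sites, against 2.38% for an even spread over 42 arrangements and 2.61% (0.541 to 7.43) in flanking windows, and 7 of the 51 lay in repeat-masked sequence. In unmatched peaks of replicate 2 the share was 17.7% (14.0 to 21.8), 69 of 390 pairs. In unmatched peaks of replicate 1 it was 5.97% (3.12 to 10.2), 12 of 201 pairs, and among those without any overlap with replicate 2 it was 4.76% (2.08 to 9.17), 8 of 168 pairs, an interval that includes the even share (p 0.0664). In replicate 2 peaks without any overlap with replicate 1 it was 18.0% (14.2 to 22.4). The reverse order, with the E-box first and the same 4 bp, came second in shared peaks, with 15 of 193 pairs (7.77%). Its share was 0.870% in flanking windows, and 4.98% and 7.18% in unmatched peaks of replicates 1 and 2. The test is of sequence alone and shows no binding by any factor.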
